A study of Mus musculus with 12 samples.

How the data were processed

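The samples were nuclei from the caudal part of the spinal trigeminal nucleus of C57BL/6 mice, in which RNA and open chromatin were read from the same nuclei (10x multiome). The 12 deposited samples were the RNA and chromatin parts of 6 libraries, 2 in each of 3 groups. CON mice received saline in the temporomandibular joint and glycerol by gavage. CFA mice received 10 µl of complete Freund's adjuvant at 5 mg/ml in the joint and glycerol by gavage. TB mice received the same adjuvant and 5 g/kg/day of tributyrin, a triglyceride that releases butyrate, for 10 days from 5 days before the injection. Tissue was taken on day 5 after the injection. The labels call a group's libraries biological replicates. Only edgeR and DESeq2 p-values measure their spread, and those of camera and Fisher's test compare genes or regions. Animals per library are not given.

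The deposited matrices hold raw counts per feature and barcode, which the authors made with Cell Ranger ARC 2.0.2 on the mouse build GRCm38/mm10 according to the submitters' processing notes. The gene values are counts of unique molecular identifiers (UMIs), and the peak values are counts in peaks called separately in each library. Whether a peak count is a cut site or a fragment is not given in the sources used here, nor is the annotation release. Each file held all barcodes, between 556119 and 676876 per library, and not only called nuclei. The RNA and chromatin samples of a library held identical files, so each library was read once. All 6 libraries listed the same 32285 genes.

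Nuclei were called in each library by 2-means clustering of the log10 counts of genes and of peaks. A nucleus was kept with at least 500 detected genes, at least 1000 peak counts and at most 5% mitochondrial UMIs. Doublets were scored with Scrublet as run by scanpy, and the highest scores were removed at a rate of 0.8% per 1000 nuclei, which took 1.69% to 5.61% of a library. This rate replaced the automatic threshold of Scrublet, which marked 0.131% of the nuclei of CON replicate 1. The nuclei left numbered 22728. Counts were scaled to a common total and log transformed, and 3000 variable genes, 30 principal components and 20 neighbours entered Leiden clustering at resolution 1. Clusters were named from 23 sets of marker genes. A cluster with Rbfox3 in at least 30% of its nuclei was taken as neuronal, unless the markers of a rarer neuron type stood out. It was excitatory or inhibitory where nuclei with the transmitter markers of one kind were at least 3 times as frequent as those of the other, and those of the other made up less than 25%. Clusters that met neither were clustered again on their own. Other clusters took the set with the highest mean log2 ratio over the mean of the clusters, if it reached 1. Left unnamed were clusters with fewer than 30 nuclei, with over 50% doublets, with no set reaching the limit, still mixed after the second clustering, or with fewer than 3 markers of their class in at least 10% of nuclei. So were clusters whose 10 leading genes held more markers of another class than of their own, and clusters of low counts with no own marker among these. This left 643 nuclei unnamed. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.

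Counts were summed per class and library. A class was tested when each library held at least 20 of its nuclei, which left excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursor cells (OPC) and microglia. Peaks of the 6 libraries were merged into 132757 regions, of which the 57704 with a peak in every library were tested. Genes and regions were fitted with edgeR 4.0.16 in R 4.3.3, with TMM normalization, its filter on low counts and quasi-likelihood F tests on all 6 libraries, which left 3 residual degrees of freedom. Adjusted p-values (Benjamini-Hochberg) were taken within a class and contrast, with a threshold of 0.05. Fold changes are given as log2 values with the standard error (SE) derived from the F statistic, and n is 2 libraries per group throughout. Levels are given in CPM (counts scaled to a common library size) with their standard deviation (SD). Class shares were tested with the same edgeR test on the number of nuclei, with the total per library as library size and adjustment over the classes of a contrast. CFA was compared with CON, TB with CFA, and TB with CON.

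Gene lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01, against the other genes of the class, and adjusted over the 82 list and class pairs of a contrast. The 25 lists were immediate early genes, neuropeptides, pain-related G protein-coupled receptors, glutamate receptors, GABA and glycine transmission, voltage-gated and TRP channels, reactive astrocyte genes, astrocyte homeostatic genes, microglia homeostatic genes, microglia activation genes, cytokines and innate signalling, interferon response, complement, myelin genes, cholesterol synthesis, OPC proliferation and differentiation, glucocorticoid response, circadian clock, heat shock and protein folding, histone deacetylases and acetyltransferases, short-chain fatty acid uptake and use, mitochondrially encoded genes, ribosomal proteins, oxidative phosphorylation and sex-linked genes. Each list was tested in the classes chosen for it.

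The groups, lists, marker sets, tests, rule for named genes and most alternatives were chosen before the data were examined. The named genes of a contrast were, in each class, the 3 rising and 3 falling genes with the smallest adjusted p among those past the threshold whose groups did not overlap, without predicted gene models. Where these came to fewer than 20, list members with the smallest unadjusted p filled the number. For each described list, 2 to 4 members were taken, and for regions the smallest adjusted p in each direction and class. Genes named outside this rule were chosen after their values were seen, and the text says so.

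The methods were tested on simulated data of the same size and depth, with 200 genes or regions changed by 1.5, 2 or 4 fold. The share recovered was 62.1% to 90.9% at 4 fold, 10.4% to 67.2% at 2 fold and 0% to 22.4% at 1.5 fold, with 1 to 12 false calls. With nothing changed, 0 to 2 were called. Among 100 unchanged lists, 0 to 4 had an unadjusted p under 0.05, and a list changed by 1.5 fold gave a p of at most 1.17e-06 in the right direction. The simulated genes were drawn independently of each other, so these values do not cover lists whose genes vary together. With the correlation estimated from the data, a changed list gave an unadjusted p between 0.00134 and 0.0336, so this form of the test is the stricter.

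The alternatives for genes were DESeq2 size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, a fit of only the 4 libraries compared, a replicate block, each library left out in turn, a minimum of 1000 genes, doublets kept, and classes subsampled to the smallest library. For regions, those that apply were run, together with a minimum of 50% of the region covered by each library's peaks and an offset for the covered length. For lists they were an estimated correlation, a replicate block and DESeq2 size factors. Chosen after seeing the data were a limit to clusters with at least 10 nuclei in every library and the subtraction of free (ambient) RNA, both for genes and lists, lists with each library left out, and a different CFA library in each contrast for the comparison of their signs. The ambient profile came from barcodes with 10 to 100 counts, and the ambient share of a class was the 0.25 quantile over markers of other classes with at least 20 expected counts. Whether replicate numbers pair libraries is unknown. Fold residuals of equal numbers correlated across genes at 0.054 to 0.20 between CON and CFA and at -0.17 to 0.064 otherwise. Groups of 2 allow no test for a deviating library or of other splits.

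Classes with fewer than 20 nuclei in a library and the unnamed nuclei were not tested for genes or regions. Motifs and footprints were not examined, since no genome sequence was at hand. Differences between classes in their response were not tested, and neither were differences between the contrasts of a class.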

Results

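RNA and open chromatin were read from single nuclei of the caudal spinal trigeminal nucleus, the brainstem relay for pain from the face and jaw. There were 2 libraries from mice with saline in the temporomandibular joint (CON), 2 from mice with complete Freund's adjuvant in the joint, which causes a lasting local inflammation (CFA), and 2 from mice with the adjuvant that also received tributyrin, a source of butyrate (TB). Libraries are named CON1 to TB2 by group and replicate. Their UMI totals were 23198519 in CON1, 20921859 in CON2, 19704403 in CFA1, 35629853 in CFA2, 51946238 in TB1 and 29730540 in TB2. The nuclei kept numbered 2990, 2248, 2042, 4530, 6624 and 4294 in the same order, with a median of 3311.5, 3733.5, 3591.5, 2916, 2972.5 and 2427.5 UMIs. Peak counts ran from 33167206 in CFA1 to 91586748 in TB1.

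Oligodendrocytes made up 44.6% of the 22728 nuclei (10131), excitatory neurons 19.8% (4506) and inhibitory neurons 16.3% (3713). Astrocytes made up 7.10% (1613), microglia 3.05% (693) and oligodendrocyte precursors (OPC) 2.63% (598). No share of these 6 classes passed the edgeR test in either main contrast. For CFA against CON the log2 ratio of shares was 0.16 ± 0.20 (SE) in excitatory neurons and -0.13 ± 0.25 in microglia, with a smallest adjusted p of 0.763. For TB against CFA it was 0.14 ± 0.19 and 0.19 ± 0.23 in these classes, with a smallest adjusted p of 0.928. The ratio of microglia changed sign without CFA1, to 0.077 for CFA against CON and to -0.015 for TB against CFA.

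**Figure D1:**
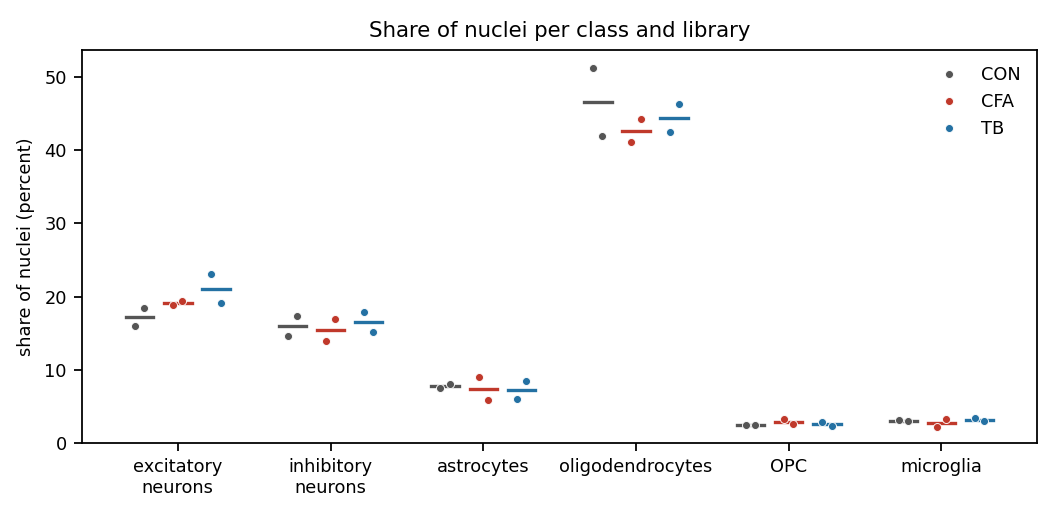
Share of each tested cell class among the nuclei of each library (percent), with 1 point per library and a bar at the mean of the 2 libraries of a group. Oligodendrocytes were the most frequent class in each library, at 41.1% to 51.3%, and no difference between groups passed the test.

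The comparison of CFA with CON asks what inflammation of the jaw joint changes in this nucleus on day 5. With edgeR on all 6 libraries, microglia, the resident immune cells, had the most called genes (60), while DESeq2 called 58 in oligodendrocytes, 32 in excitatory neurons and 21 in microglia. Apoe (ENSMUSG00000002985, chromosome 7), a lipid carrier that rises in activated microglia, rose by 3.74 ± 0.39 in log2, from 183 and 127 CPM in the CON libraries to 890 and 3114 CPM in the CFA libraries (adjusted p = 9.51e-07). Lyz2 (ENSMUSG00000069516, chromosome 10), a lysozyme of phagocytes, rose by 2.60 ± 0.40. Ccl12 (ENSMUSG00000035352, chromosome 11), a monocyte-attracting chemokine, rose by 4.46 ± 0.71 from levels of 0 and 18.1 CPM, with a fold that depended on these (3.35 without CON1 and 7.99 without CON2). Fkbp5 (ENSMUSG00000024222, chromosome 17), a co-chaperone that glucocorticoids induce, fell by 2.40 ± 0.32 on the log2 scale, and Mt1, a metallothionein, rose by 1.89 ± 0.36. Smarca5, a chromatin remodeller, fell by 2.25 ± 0.50, and Rcsd1, an actin-capping regulator, fell by 1.34 ± 0.30. The cytochrome oxidase genes mt-Co1, mt-Co2 and mt-Co3 rose by 1.88, 1.49 and 1.46, mt-Atp6 and mt-Cytb by 1.53 and 1.64, and the ribosomal protein gene Rpl38 by 1.74. In each of these genes both CFA libraries lay on the same side of both CON libraries.

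The microglia activation list rose as a group (adjusted p = 1.14e-14, 0.397 with an estimated correlation). All 12 measured members had a positive fold change (median 0.83), 3 passed over all genes (Apoe, Lyz2 and Fth1) and 9 when adjusted over the list alone. Fth1, a ferritin chain also called in OPC, rose by 1.31 ± 0.25 (0.56, not called, without free RNA). B2m, of the class I antigen complex, stood at 1.06 ± 0.29. The interferon response list also passed in microglia, with 12 of 14 members positive (median 0.60), 1 past over all genes and 3 when adjusted over the list alone. Its adjusted p was 4.38e-04, but 0.437 with an estimated correlation and 0.856 without CFA2. Its leading members were Bst2, a tether of budding viruses, at 2.24 ± 0.55 and Rnf213, an antimicrobial ubiquitin ligase, at 1.17 ± 0.34. The homeostatic, complement and cytokine lists of microglia did not pass (adjusted p = 0.88, 0.147 and 0.795).

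In all, 54 genes rose and 6 fell in microglia of 4258 tested with edgeR, 23 of them ribosomal protein genes, 9 mitochondrially encoded and 28 others. The estimated share of free RNA in microglia also differed, with means of 0.446% in CON, 3.38% in CFA and 6.71% in TB. After subtraction of free RNA, 59 of the 60 genes kept their sign and 5 passed, among them Apoe at 3.78, Lyz2 at 2.60, Ccl12 at 4.47 and Fkbp5 at -2.35. The count was 21 by DESeq2, 23 in subsampled classes, 11 without CON1, 7 without CFA2 and 134 without CFA1. Without CFA2 the calls of Ccl12 (3.62), Smarca5 (-1.96), Rcsd1 (-1.04), Mt1 (1.91), Rpl38 (1.61), mt-Atp6 (1.14) and mt-Cytb (1.32) ended. Without CON1 those of Smarca5 (-2.37), Rcsd1 (-1.15), Mt1 (1.76), Rpl38 (1.64) and mt-Cytb (1.45) ended, and without CON2 that of Smarca5 (-2.16). The calls of Apoe, Lyz2, Fkbp5, mt-Co1, mt-Co2 and mt-Co3 held without each library, but the size of the folds moved. That of Apoe ran from 2.46 (without CFA2) to 4.28 (CFA1), that of Lyz2 from 2.12 (CON1) to 3.12 (CON2) and that of Fkbp5 from -2.93 (CFA1) to -1.76 (CFA2).

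**Figure D2:**
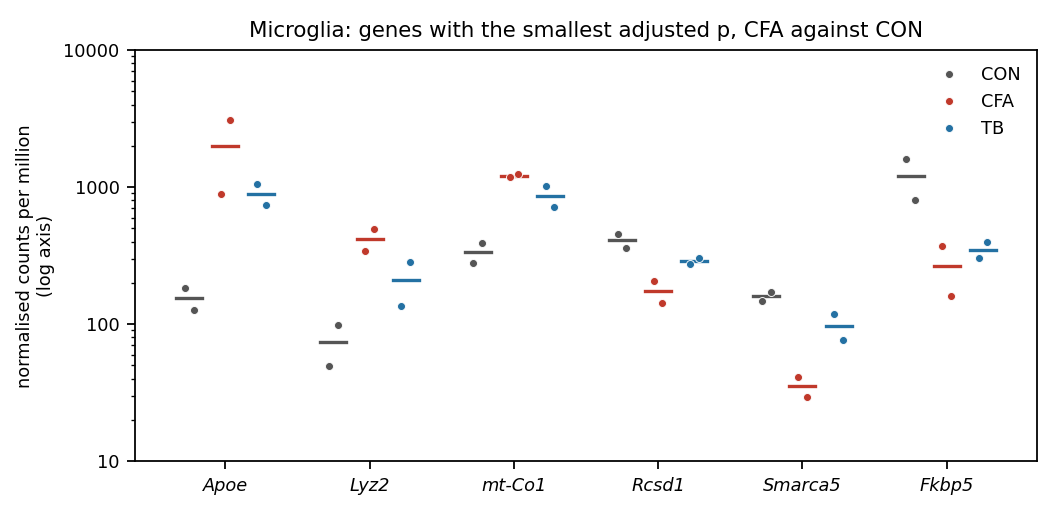
Level of 6 genes in microglia (CPM, log axis), with 1 point per library and a bar at the mean of each group of 2 libraries. Apoe lay at 183 and 127 in CON and at 890 and 3114 in CFA, and Fkbp5 at 1608 and 805 in CON and at 370 and 162 in CFA.

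In oligodendrocytes, the myelin-forming cells, the glucocorticoid response list was lower with CFA (14 of 18 measured members negative, median -0.63, adjusted p = 7.82e-15, 0.397 with an estimated correlation). Sgk1 (ENSMUSG00000019970, chromosome 10), a kinase that glucocorticoids induce, fell by 1.54 ± 0.19 on the log2 scale, from 605 and 517 CPM to 240 and 150 CPM (adjusted p = 0.0453). Arl4d, a small GTPase, fell by 1.55 ± 0.20 on the log2 scale, and Cdr2, a cytoplasmic antigen that binds Myc, fell from 55.5 and 51.0 CPM to 20.6 and 17.6 CPM, at the same adjusted p. Of the list members 1 fell over all genes, and adjusted over the list alone 10 fell and 2 rose, the metallothioneins Mt1 and Mt2. Ddit4, an inhibitor of mTOR signalling, stood at -1.19 ± 0.18, Nfkbia, an inhibitor of NF-κB, at -1.41 ± 0.25, and Arrdc2, an arrestin-like protein, at -0.96 ± 0.18. The list held at the preset correlation without each library and after free RNA was subtracted, and a shift between clusters stays open for it.

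**Figure D3:**
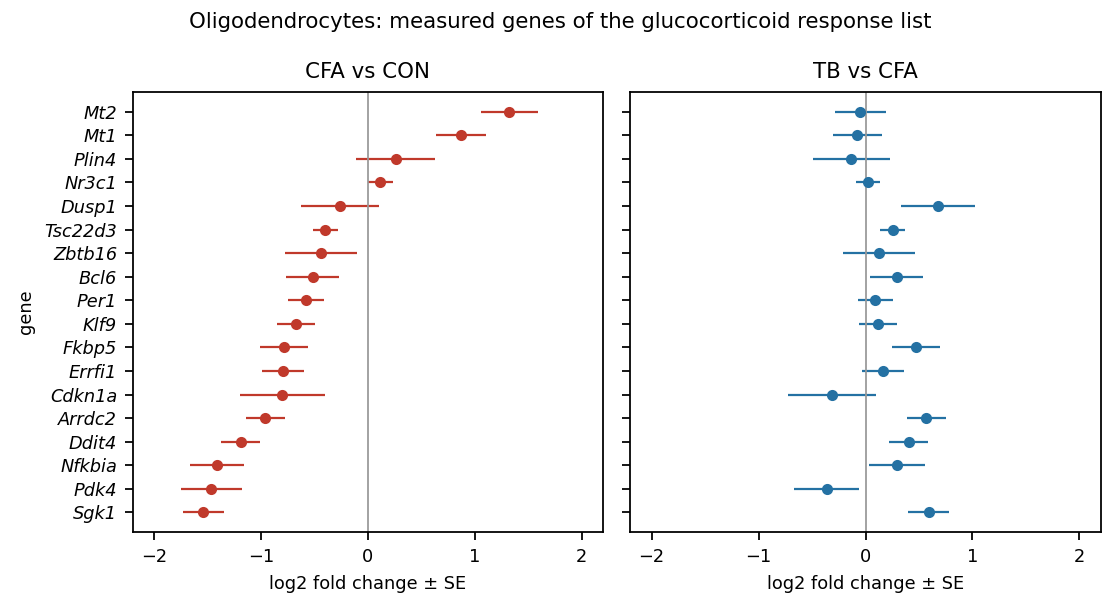
Log2 fold change (± SE, 2 libraries per group) of the 18 measured glucocorticoid response genes in oligodendrocytes for CFA against CON and for TB against CFA. Sgk1 lay at -1.54 and 0.59 in the 2 contrasts, and 14 of the 18 genes lay below 0 for CFA against CON.

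Of 49836 regions tested in oligodendrocytes, 317 were less and 27 more open with CFA. They were tested on the whole class and not within its clusters. The shares of these clusters differed between libraries, so a shift between clusters stays open for the regions. The falling regions had a median log2 fold change of -0.76 and the rising ones of 0.85. Of the 344, 79 lay within 1000 bases of a gene start and 245 within a gene body. The region with the smallest adjusted p (6.77e-11) lay inside Zbtb16, a transcription factor that glucocorticoids induce, at chromosome 9, 48735969 to 48736793, 99151 bases from its start, and fell by 1.91 ± 0.15. Among the falling regions, 17 had a glucocorticoid response gene as the nearest start, 6 of them Zbtb16 and 3 Sgk1, against 65 of the 49519 other tested regions. The region with the smallest adjusted p among the rising ones lay at Zfp36l2, which encodes an mRNA decay factor, at chromosome 17, 84187736 to 84188767, and rose by 0.69 ± 0.09, but not with the covered length as an offset (adjusted p = 0.855). The count of regions was 310 with the offset and 374 where each library's peaks covered 50% of the region, and it was 125 without CON1 and 130 without CFA2.

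The 3 genes called in oligodendrocytes were few beside 935 at an unadjusted p under 0.05 and 58 called by DESeq2 (37 rising and 21 falling). The edgeR count fell to 0 without CON1, without CON2 or without CFA2, to 1 without CFA1, to 0 with doublets kept and to 0 after free RNA was subtracted (adjusted p = 0.0558 for all 3), and it was 79 without TB1 and 101 without TB2. The call of Sgk1 held without CFA1 (-1.89) and ended without CON1 (-1.42), CON2 (-1.63) and CFA2 (-1.22). OPC had 6 rising genes of 6265 tested. Fth1 rose by 1.35 ± 0.21, and Rplp1 and Rpl37, proteins of the large ribosomal subunit, rose by 1.49 ± 0.27 and 1.66 ± 0.31. Also among the 6, and named after their values were seen, were the myelin gene Mbp at 1.10 ± 0.22 and Ndufa4, a respiratory chain subunit, at 1.46 ± 0.31. The estimated share of free RNA in OPC was 1.90% in CON and 4.89% in CFA. After its subtraction 2 genes passed in OPC, and none of the 6 was among them, of which 2 had too few counts left to be tested. The rising genes had a median of 1.41 before and 1.27 after, and the 4 still tested kept their sign. The count was 0 by DESeq2 (510 at an unadjusted p under 0.05), 21 without CON2, 50 without CFA1, 1 without CFA2 and 34 without TB2, and the calls of Fth1 (0.97), Rplp1 (1.17) and Rpl37 (1.34) ended without CFA2, that of Rpl37 (1.19) also without CON1.

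In neurons no single gene passed with edgeR. Excitatory neurons had 698 genes at an unadjusted p under 0.05 and 32 calls by DESeq2, all rising, and inhibitory neurons had 425 and 3. Without TB1 the edgeR counts were 57 and 34, and without TB2 they were 52 and 32. The excitatory class was not made up alike in all libraries. Cluster 27 held 0.628% and 0.726% of it in CON, 9.87% and 6.70% in CFA, and 0.392% and 4.52% in TB. Lists were therefore also tested on clusters with at least 10 nuclei in every library, a limit chosen after the data were seen. Immediate early genes, which neurons switch on with activity, were lower in excitatory neurons (13 of 19 negative, median -0.34, adjusted p = 4.8e-05, 0.437 with an estimated correlation). They were also lower in inhibitory neurons (13 of 18 negative, median -0.38, adjusted p = 4.86e-07, 0.397 with an estimated correlation). In each class 1 member fell when adjusted over the list alone and 0 over all genes by edgeR. On the shared clusters the list passed in both classes (adjusted p = 4.39e-05 and 9.58e-08). Fos stood at -1.23 ± 0.39 in excitatory and -1.31 ± 0.48 in inhibitory neurons, Homer1, a synaptic scaffold, at -0.48 ± 0.10 and -0.31 ± 0.11, and the nuclear receptor Nr4a3 at -3.18 ± 0.75 in inhibitory neurons.

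Neuropeptides were higher in inhibitory neurons, with 16 of 17 members positive (median 0.70), 2 rising when adjusted over the list alone and 0 over all genes by edgeR. The list passed (adjusted p = 1.35e-12, 0.397 with an estimated correlation). Galanin (Gal) stood at 1.26 ± 0.33, Cartpt at 1.61 ± 0.42, neurotensin (Nts) at 1.88 ± 0.59 and Pnoc, the nociceptin precursor, at 0.76 ± 0.27. Gal, Cartpt and Nts were also leading genes of excitatory clusters, and Gal and Pnoc of inhibitory cluster 31. Free RNA or a shift between clusters stays open for these genes. In excitatory neurons the list passed (14 of 21 positive, median 0.32, adjusted p = 0.0132, 0.484 with an estimated correlation) but not without CON1 (adjusted p = 0.22) or CFA2 (0.313). Crh, the stress peptide corticotropin-releasing hormone, stood at 2.28 ± 0.53 and Npy at 1.09 ± 0.50. Pain-related receptors passed as lower in excitatory neurons (17 of 23 negative, median -0.17, adjusted p = 0.0249, 0.478 with an estimated correlation), with the prostaglandin receptor Ptger3 at -1.21 ± 0.38 and the μ opioid receptor Oprm1 at -0.29 ± 0.11, but not without CON1 (adjusted p = 0.168) or CFA2 (0.192). Glutamate receptors passed in inhibitory neurons (20 of 24 positive, median 0.06, adjusted p = 0.0279, 0.691 with an estimated correlation), but not without CON2 (adjusted p = 0.171) or CFA1 (0.98). Clock genes were lower in excitatory neurons (median -0.13, adjusted p = 0.0105, 0.437 with an estimated correlation), but not without CON2 (adjusted p = 0.321) or CFA1 (0.0532). On the shared clusters neuropeptides passed in excitatory (adjusted p = 4.39e-05) and inhibitory neurons (1.34e-05), as did pain-related receptors (0.0186), clock genes (7.22e-04) and glutamate receptors (0.0144) in the classes named.

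Astrocytes had 0 genes past the threshold with edgeR, 844 at an unadjusted p under 0.05 and 0 by DESeq2, and the edgeR count was 1 without CON1, 1 without CFA2, 22 without CFA1, 127 without TB1 and 153 without TB2. Their heat shock and protein folding list rose (20 of 23 positive, median 0.41, 2 when adjusted over the list alone, adjusted p = 5.62e-04, 0.437 with an estimated correlation), with the chaperones Hsp90ab1 at 1.01 ± 0.25 and Hspa8 at 0.85 ± 0.23. Cholesterol synthesis genes were lower in astrocytes (19 of 23 negative, median -0.45, adjusted p = 1.22e-04, 0.437 with an estimated correlation), with the enzymes Nsdhl at -0.75 ± 0.28 and Cyp51 at -0.61 ± 0.24, but not without CON2 (adjusted p = 0.106). The same list was lower in excitatory (median -0.15, adjusted p = 0.0117) and inhibitory neurons (median -0.087, adjusted p = 0.0249), each with 0.437 as the adjusted p with an estimated correlation. It did not pass there without CON2 (adjusted p = 0.563 and 0.49) or CFA1 (0.0915 and 0.253), nor in inhibitory neurons on the shared clusters (0.165). Glucocorticoid response genes were lower in astrocytes (14 of 16 negative, median -0.29, adjusted p = 0.00977, 0.397 with an estimated correlation) and OPC (7 of 10 negative, median -0.42, adjusted p = 0.0434, 0.437 with an estimated correlation). These calls ended without CON1 (adjusted p = 0.0721 and 0.23) and without CFA2 (0.187 and 0.306). The interferon list passed in oligodendrocytes (8 of 11 positive, median 0.66, adjusted p = 0.00361, 0.484 with an estimated correlation) with Ifit2 at 1.72 ± 0.44, but turned without CFA2 (adjusted p = 0.631). Heat shock genes passed in OPC (16 of 20 positive, median 0.43, adjusted p = 4.84e-05, 0.437 with an estimated correlation) but not without CFA2 (adjusted p = 0.183), with the chaperone Hspa5 at 1.34 ± 0.38.

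Ribosomal protein genes were higher in each tested class, with medians of 0.56 in excitatory neurons, 0.52 in inhibitory neurons, 0.93 in astrocytes, 0.73 in oligodendrocytes, 0.86 in OPC and 1.19 in microglia. These and the mitochondrial and oxidative phosphorylation lists below passed in each class tested, with adjusted p between 2.75e-46 and 1.22e-04, and none did with an estimated correlation (adjusted p = 0.397 to 0.437). All 46 members were positive except 1 in OPC. Adjusted over the list alone 28, 8, 38, 42, 28 and 38 rose in these classes, and over all genes 2 in OPC and 16 in microglia. The mitochondrially encoded list had medians of 0.35, 0.22, 0.72, 0.77, 0.36 and 1.48, and oxidative phosphorylation genes, tested in the first 4 of these classes, had medians of 0.48, 0.37, 0.64 and 0.68, with 0, 0, 2 and 24 members rising when adjusted over the list alone. The free RNA of the libraries moved with them, from 2.32% in CON to 4.36% in CFA in oligodendrocytes, 1.35% to 2.47% in excitatory neurons and 2.29% to 3.70% in astrocytes. After its subtraction the ribosomal call ended in OPC (adjusted p = 0.958), and that of mitochondrial genes ended in astrocytes (median 0.24, adjusted p = 0.467) and microglia (median 0.70, adjusted p = 0.929). In neurons, oligodendrocytes and OPC the subtraction took mitochondrial counts near 0 in some libraries (medians from -9.76 to -2.60), so that their folds could not be read. The calls ended without CFA2 for oxidative phosphorylation (adjusted p = 0.207) and mitochondrial genes (0.0764) in inhibitory neurons and for mitochondrial genes in OPC (0.308), the last also without CON2 (0.196).

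Of the 82 list and class pairs, 37 passed for CFA against CON, 24 up and 13 down, of which 20 held without each library, 30 after subtraction of free RNA and 15 under both. The limit to shared clusters left out clusters only in neurons, where 14 of the 16 pairs that passed held. With an estimated correlation 0 passed with camera (smallest adjusted p = 0.397), against 37 at the preset correlation, where 43 had an unadjusted p under 0.05. The measured sex-linked genes, all on the Y chromosome in these classes, were lower in oligodendrocytes (4 of 4 negative, median -0.28, adjusted p = 0.00222), astrocytes (median -0.46, adjusted p = 0.00635) and inhibitory neurons (median -0.17, adjusted p = 0.0434), where the adjusted p with an estimated correlation was 0.397, 0.397 and 0.484. Of these calls, that in astrocytes ended without CON2 (adjusted p = 0.0797) and that in inhibitory neurons without CON2 (0.321), on the shared clusters (0.0747) and, turning, without CFA2 (0.973). Lists of inhibitory transmission, voltage-gated channels, reactive and homeostatic astrocyte genes, myelin genes and OPC genes did not pass (adjusted p = 0.0859 to 0.825). Histone deacetylases and acetyltransferases, of which butyrate inhibits some, and genes of short-chain fatty acid uptake and use did not pass either (adjusted p from 0.0786 to 0.891 and from 0.0583 to 0.88). The test and the median differed in sign for voltage-gated channels in excitatory neurons (test up, median -0.026), clock genes in oligodendrocytes and OPC, cytokine genes in astrocytes and microglia, homeostatic genes in microglia and deacetylases in excitatory neurons. None of these passed.

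**Figure D4:**
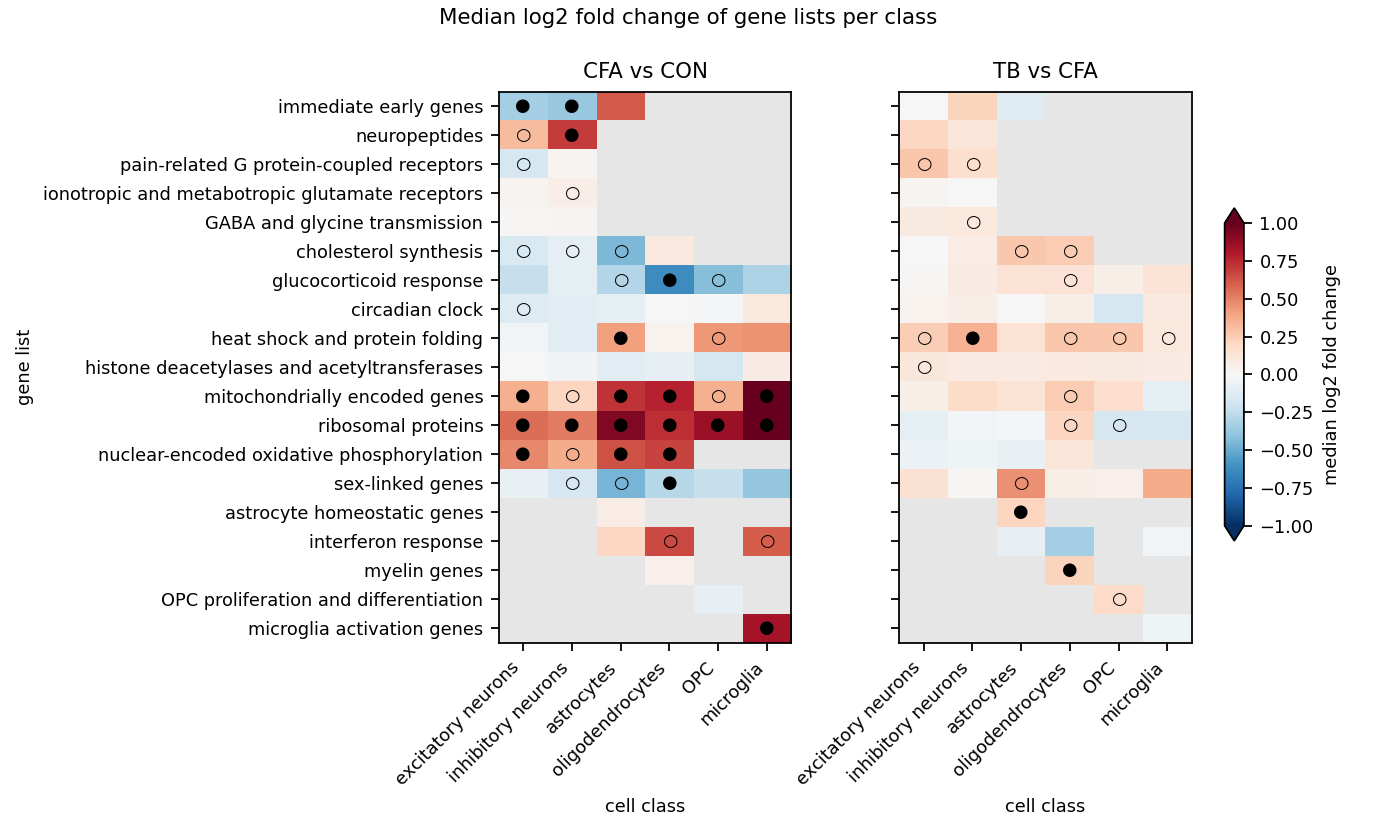
Median log2 fold change of the gene lists that passed in at least 1 class (vertical axis) in each cell class (horizontal axis) for CFA against CON and for TB against CFA, with grey where a list was not assigned to a class. Filled circles mark an adjusted p under 0.05 that held without each library (20 and 3 pairs) and open circles one that did not hold.

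Fewer regions changed in the other classes. In microglia the region 170 bases from the start of Fkbp5 (chromosome 17, 28517695 to 28518571) fell by 1.71 ± 0.30 (adjusted p = 0.0255), and a region in Ppp2r5e (chromosome 12, 75448670 to 75450398) rose by 3.34 ± 0.59. In astrocytes 26 regions fell and 4 rose, among them a rise of 1.03 ± 0.15 near Notch1, a receptor in cell fate choice (chromosome 2, 26499854 to 26501108), and a fall of 1.60 ± 0.24 near Nepro (chromosome 16, 44716116 to 44717287). Excitatory neurons had 5 regions, with a fall of 0.95 ± 0.14 at Sbf2 (chromosome 7, 110614145 to 110615178) and a rise of 1.65 ± 0.30 at Zfp36l2, and inhibitory neurons had 4, with a fall of 1.23 ± 0.17 at B3gnt9 (chromosome 8, 105254052 to 105255339). OPC had 0 by edgeR, with 1742 at an unadjusted p under 0.05. With the covered length as an offset, 0 remained past the threshold in either class of neurons, 12 in astrocytes, without the regions near Notch1 (adjusted p = 0.603) and Nepro (0.284), and 1 in microglia, the region at Fkbp5 (adjusted p = 0.0392). Leaving out a library moved the counts to 0 (CFA1) and up to 24 (CON2) in excitatory neurons, 8 (CON1 or CFA1) in inhibitory neurons, 17 (CON1), 12 (CON2) and 67 (CFA1) in astrocytes, 13 (CON1) in OPC, and 12 (CON1), 11 (CON2) and 1 (CFA1) in microglia. Across genes, which are not independent replicates, the fold change of a gene and of the region at its start had a Spearman correlation of 0.105 in oligodendrocytes and between -0.00983 and 0.0783 in the other classes. All 3 genes called in oligodendrocytes had a promoter region of the same sign, as did 26 of the 43 called in microglia and 2 of the 5 in OPC that had such a region. For TB against CFA 0 of the 2 genes called in OPC did.

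The comparison of TB with CFA asks what tributyrin changes in mice with an inflamed joint. With edgeR on all 6 libraries, 4 genes passed, in OPC and microglia. Gpr17 (ENSMUSG00000052229, chromosome 18), a receptor and leading gene of the committed precursor class, rose in OPC by 1.39 ± 0.24, from 162 ± 59.9 (SD) to 409 ± 79.2 CPM (adjusted p = 0.00328). A shift between these classes was not tested. Malat1, an abundant nuclear noncoding RNA, fell in OPC by 0.70 ± 0.13 (adjusted p = 0.00714). In microglia the neuronal adhesion gene Lsamp rose by 3.35 ± 0.49 (adjusted p = 3.36e-04), while the share of free RNA was 3.38% in CFA and 6.71% in TB. Lsamp had too few counts for a test after subtraction. DESeq2 called 0 genes in OPC and 2 in microglia. The call of Gpr17 ended without CFA2 (1.01) and TB1 (1.14) and that of Malat1 without TB1 (-0.51). With doublets kept both ended (1.31 and -0.69), and that of Malat1 also with a replicate block (-0.69) and in a fit of only the 2 groups (-0.71). The count in OPC was 6 without CON1, CFA1 or CFA2, 7 without CON2, 0 without TB1 and 40 without TB2, and in microglia 7 without CON1 or CON2, 4 without CFA2, 15 without TB2 and 25 with doublets kept.

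In the other classes edgeR called 0 genes for TB against CFA. At an unadjusted p under 0.05 there were 1405 in excitatory neurons, 1277 in inhibitory neurons, 513 in astrocytes and 1074 in oligodendrocytes, and DESeq2 called 5, 1, 0 and 3. Without TB2 the counts were 1517 (657 rising and 860 falling), 1635 (715 and 920), 67 and 582 (274 and 308), so these counts rested on whether TB2 was in the fit. Without TB1 it was 2 in inhibitory neurons, and without CFA1 it was 1 in astrocytes. The Apoe and Lyz2 of microglia stood at -1.21 ± 0.30 and -1.15 ± 0.31 and did not pass (adjusted p = 0.184 and 0.329), and without CFA2 Apoe stood at 0.057. List members with a small unadjusted p that did not pass (adjusted p = 0.48 to 0.589) included Gad1, which makes GABA, at 0.51 ± 0.11 and the calcium channel Cacna1d at -0.40 ± 0.09 in inhibitory neurons. They also included the GABA receptor subunit Gabrg1 at -0.96 ± 0.22, the potassium channel Kcna2 at 0.72 ± 0.18, Arrdc2 at 1.52 ± 0.39 and Rps27 at -0.57 ± 0.13 in excitatory neurons, and the mitochondrial chaperone Hspd1 at 1.99 ± 0.59 and the lineage factor Nkx2-2 at 0.93 ± 0.31 in OPC.

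Chaperone, myelin and astrocyte lists were higher with tributyrin. Heat shock and protein folding genes were higher in inhibitory neurons (23 of 27 positive, median 0.35, 5 past when adjusted over the list alone and 0 over all genes by edgeR, adjusted p = 4.85e-08, 0.942 with an estimated correlation). Hspa8, the main constitutive chaperone, stood at 0.68 ± 0.15, Hsp90b1 at 0.56 ± 0.13 and Hspa5, a chaperone of the endoplasmic reticulum, at 0.65 ± 0.17. Myelin genes were higher as a list in oligodendrocytes (16 of 21 positive, median 0.22, adjusted p = 6.25e-05, 0.942 with an estimated correlation), with the myelin enzyme Cnp at 0.59 ± 0.17 and the lineage factor Olig1 at 0.45 ± 0.14. Homeostatic genes were higher as a list in astrocytes (15 of 16 positive, median 0.21, adjusted p = 1.07e-04, 0.942 with an estimated correlation), with the amino acid transporter Slc7a10 at 0.56 ± 0.17, Fgfr3 at 0.39 ± 0.16 and the gap junction protein Gja1 at 0.35 ± 0.16. These 3 lists held without each library and after subtraction of free RNA at the preset correlation. No myelin or astrocyte member passed on its own, with 0 over all genes by edgeR and 0 when adjusted over the list alone.

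A further 16 lists passed for TB against CFA but not without every library, and each had an adjusted p of 0.942 with an estimated correlation. Cholesterol synthesis genes were higher in oligodendrocytes (24 of 24 positive, median 0.25, adjusted p = 1.63e-04, 0.0781 without TB1) and astrocytes (21 of 23 positive, median 0.27, adjusted p = 0.00137, 0.237 without TB2), with Cyp51 at 0.48 ± 0.15 and Hmgcs1 at 0.45 ± 0.15 in oligodendrocytes. Heat shock genes were higher in excitatory neurons (median 0.25, adjusted p = 5.36e-06, 0.128 without TB2), oligodendrocytes (median 0.28, adjusted p = 4.83e-06, 0.211 without CFA1 and 0.0912 without TB2), OPC (median 0.27, adjusted p = 0.0321, 0.934 without CFA1, where the test turned and the median was 0.069, and 0.203 without TB2) and microglia (median 0.11, adjusted p = 0.0472). In oligodendrocytes Hspa8 stood at 0.84 ± 0.17, Hsph1 at 0.67 ± 0.17 and Hsp90aa1 at 0.62 ± 0.17. The microglial call ended without CON1 (adjusted p = 0.0507), CON2 (0.0605), CFA1 (0.344) and TB2 (0.214), and after subtraction of free RNA (0.0686). Pain-related receptors were higher in excitatory neurons (19 of 23 positive, median 0.28, adjusted p = 0.00641, 0.0684 without CFA2 and 0.0957 without TB1) and inhibitory neurons (median 0.17, adjusted p = 0.0221, 0.517 without TB1), with Ptger3 at 1.15 ± 0.37, the substance P receptor Tacr1 at 0.55 ± 0.19 and the κ opioid receptor Oprk1 at 0.51 ± 0.19 in excitatory neurons. GABA and glycine genes were higher in inhibitory neurons (16 of 26 positive, median 0.10, adjusted p = 0.0102, 0.0774 without CFA2 and 0.433 without TB1), with Gad1 past when adjusted over the list alone.

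OPC genes were higher in OPC (12 of 17 positive, median 0.19, adjusted p = 0.00421, 0.942 with an estimated correlation, as for each list below), with Gpr17 and Nkx2-2 past when adjusted over the list alone, but not without CON2 (adjusted p = 0.0501), CFA1 (0.352) or TB1 (0.249). Histone deacetylases and acetyltransferases were higher in excitatory neurons (22 of 27 positive, median 0.11, adjusted p = 0.0321), with Hdac2 at 0.31 ± 0.13 and Sirt2 at 0.30 ± 0.13, but not without CFA2 (adjusted p = 0.208) or TB1 (0.536). Glucocorticoid response genes were higher in oligodendrocytes (13 of 18 positive, median 0.14, adjusted p = 0.0371), with Sgk1 at 0.59 ± 0.19 and Arrdc2 at 0.57 ± 0.18, but not without CON1 (adjusted p = 0.0507), CON2 (0.0828), CFA2 (0.599) or TB2 (0.367). In oligodendrocytes mitochondrial genes passed (median 0.25, adjusted p = 0.036, but 0.0507 without CON1, 0.0585 without CON2, 0.904 without CFA1 and, turning, 0.738 without TB1), and so did ribosomal proteins (median 0.21, adjusted p = 0.00372), turning at 0.0514 without CFA1 and 0.709 without TB2. Ribosomal proteins in OPC were lower (median -0.17, adjusted p = 0.0221), turning at 0.83 without CFA2, 0.756 without TB1 and 9.72e-10 after subtraction of free RNA. The sex-linked genes measured, all Y-linked, were higher in astrocytes (4 of 4 positive, median 0.46, adjusted p = 0.00564, 0.0684 without CFA2 and 0.0813 without TB1), with Eif2s3y at 0.73 ± 0.22. In all 19 lists passed, 18 up and 1 down, of which the 6 in neurons also passed on the shared clusters, and 0 passed with camera at an estimated correlation. Lists that did not pass included immediate early genes (adjusted p = 0.187 to 0.705), neuropeptides (0.096 and 0.652), glutamate receptors (0.577 and 0.652), voltage-gated channels (0.096 and 0.298), reactive astrocyte genes (0.13), microglia activation (0.582) and homeostatic genes (0.0877), cytokines (0.395 and 0.774), interferon response (0.423 to 0.944), complement (0.738 and 0.549), oxidative phosphorylation (0.107 to 0.86), clock genes (0.378 to 0.903) and short-chain fatty acid genes (0.729 to 0.919). The test and the median differed in sign for short-chain fatty acid genes and oxidative phosphorylation in inhibitory neurons (medians -0.035 and -0.045) and interferon response in microglia (-0.024).

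Regions changed in small numbers with tributyrin, 7 in excitatory neurons (5 rising), 6 in inhibitory neurons (5 rising), 5 in astrocytes (4 rising), 12 in oligodendrocytes (11 rising) and 4 in OPC (all rising). The region at B3gnt9, a glycosyltransferase gene, rose by 1.08 ± 0.15 in excitatory and 1.17 ± 0.16 in inhibitory neurons, and that at Hecw1, a ubiquitin ligase gene (chromosome 13, 14521705 to 14523565), fell by 1.10 ± 0.13 and 1.22 ± 0.15. The region at Zfp36l2 fell by 0.57 ± 0.08 in oligodendrocytes and one near Gm2447 (chromosome 3, 52644063 to 52645070) rose by 0.94 ± 0.10. In astrocytes a region near Lyzl1 (chromosome 18, 3969325 to 3970880) rose by 1.66 ± 0.24 and one at Eva1a (chromosome 6, 82041181 to 82043338) fell by 1.24 ± 0.18. In OPC the region at Gm10800 (chromosome 2, 98666824 to 98667421), a site known for high signal in chromatin data, rose by 1.57 ± 0.16. Microglia had 0 by edgeR and 651 at an unadjusted p under 0.05. With the covered length as an offset 0 passed in neurons and astrocytes, 3 in oligodendrocytes, without the regions at Zfp36l2 (adjusted p = 0.976) and Gm2447 (0.838), and 4 in OPC, among these the one at Gm10800 (adjusted p = 3.44e-10). Leaving out a library moved the counts to 20 (CON1), 14 (CON2), 13 (CFA2 or TB1) and 3 (TB2) in excitatory neurons, 12 (CFA1) in inhibitory neurons, 19 (CFA1), 18 (CFA2), 9 (TB1) and 12 (TB2) in astrocytes, 27 (CON1 or TB1), 30 (CON2), 24 (CFA1), 39 (CFA2) and 26 (TB2) in oligodendrocytes, 8 (CON1 or CON2), 9 (TB1) and 2 (TB2) in OPC, and 3 (CFA2) and 1 (TB2) in microglia.

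A further question is whether tributyrin reverses what the adjuvant changed. Of the 60 genes called in microglia for CFA against CON, 55 (91.7%) had the opposite sign for TB against CFA, with the rising genes at a median of 1.65 in the first contrast and -0.31 in the second and the falling genes at -1.42 and 0.70. The CFA libraries enter both contrasts with opposite signs, so that opposite signs arise with no effect of tributyrin. With a different CFA library in each contrast, a test chosen after these signs were seen, the result depended on which library was used. Genes called in microglia with CFA2 had the opposite sign against CFA1 in 37 of 132 cases (28.0%), and those called with CFA1 had it against CFA2 in 6 of 7. Apoe stood at 4.28 with CFA2 and, for TB against CFA1, at 0.057. The fold changes of all genes then correlated between -0.145 and -0.0484 over the classes in the split with CFA1 first and between 0.0569 and 0.276 in the other, so a reversal by tributyrin is not shown. Across genes, which are not independent replicates, the fold changes of both contrasts correlated at -0.382 in microglia, -0.405 in OPC, -0.305 in excitatory neurons, -0.232 in inhibitory neurons, -0.314 in astrocytes and -0.0873 in oligodendrocytes, all closer to 0 than the -0.498 to -0.532 of simulated counts without any group effect. The covariance was slightly more negative than simulated in OPC (-0.0829 against -0.0793 ± 0.00246) and microglia (-0.103 against -0.0959 ± 0.00373, SD over simulations), and less negative in the other classes. No gene passed in both contrasts with opposite signs in edgeR, where chance gave 0.000958 in OPC and 0.00282 in microglia. In TB against CON, edgeR called 63 genes in microglia (54 rising and 9 falling), 11 in OPC, 1 in oligodendrocytes and 0 in excitatory neurons, inhibitory neurons and astrocytes (1623, 1740 and 1199 at an unadjusted p under 0.05), and 422 regions in oligodendrocytes (103 rising and 319 falling), 55 in astrocytes, 6 in excitatory neurons, 2 each in inhibitory neurons and OPC and 1 in microglia.

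**Figure D5:**
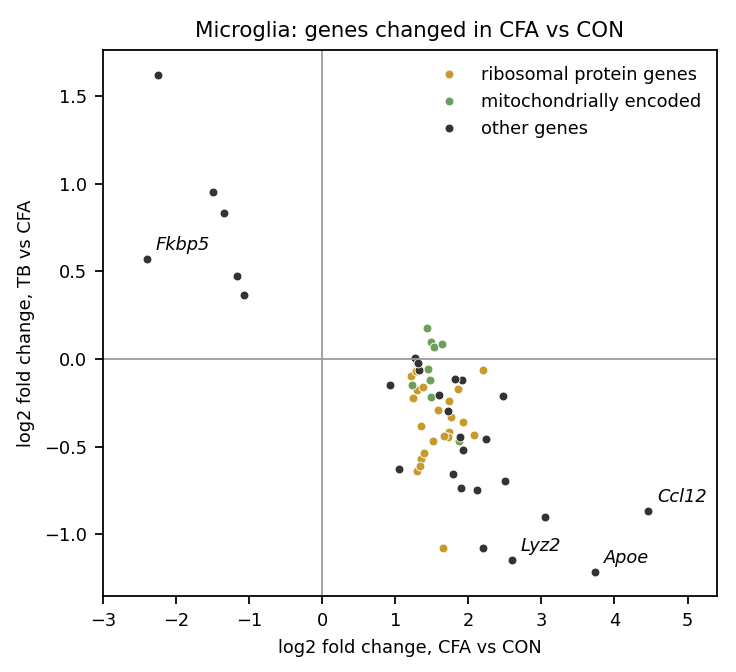
Log2 fold change of the 60 genes called in microglia for CFA against CON (horizontal axis) and for TB against CFA (vertical axis), with 1 point per gene and 2 libraries per group. Of the 60, 55 lay on opposite sides of 0 in the 2 contrasts, as the shared CFA libraries favour.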

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

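The tests of free RNA and of oligodendrocyte genes and regions below were chosen after the results were seen, except those of the clusters that hold the glucocorticoid list and of the excitatory calls without TB2.

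Some values lay above the CON level in data that the comparisons of genes and regions did not use. Endothelial cells made up a mean of 1.39% of the nuclei in CFA against 0.685% in CON, and pericytes 0.812% against 0.334%. The estimated share of free RNA had a mean in CFA of 2.47% in excitatory neurons against 1.35% in CON, 2.14% in inhibitory neurons against 1.56%, 3.70% in astrocytes against 2.29%, 4.36% in oligodendrocytes against 2.32%, 4.89% in OPC against 1.90% and 3.38% in microglia against 0.446%. These differences were not tested.

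Microglia with CFA had more RNA of activation, ribosomal and mitochondrial genes, which free RNA or border macrophages within the class could account for. After subtraction of free RNA the smallest log2 fold change of Apoe, Lyz2 and Ccl12 was 2.60, which argues against free RNA for these. Called ribosomal protein genes, picked by this contrast, had a median of 1.23 against 1.51 before (SE 0.0776). The activation list had a median of 0.63 against 0.83 before (SE 0.372). It stayed past the threshold at the preset correlation (adjusted p = 1.17e-11, against 0.397 before subtraction with an estimated correlation). The called mitochondrial genes fell to 0.70 from 1.48 (SE 0.0957), and free RNA stays open for these, the ribosomal genes and the list. Folds of macrophage markers could not be read at 0 to 3 counts. In a test chosen after these were seen, macrophages bringing the rise of Apoe would have given 505 marker counts, where 3 were seen. The ribosomal and mitochondrial lists were drawn up as RNA that nuclei carry over from cytoplasm, and ribosomal genes rose in each tested class. The median mitochondrial share of the nuclei was 0.140% and 0.130% in CON and 0.216% and 0.264% in CFA. Such carry-over was not tested and stays open for these genes. A response of microglia to the inflamed joint stays possible and was not tested apart from these explanations.

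Glucocorticoid response genes were lower in oligodendrocytes of the CFA libraries, which a shift between clusters of the class, free RNA or a weaker glucocorticoid response could account for. Over 5 clusters the median log2 fold change of the list ran from -0.66 to -0.27, against -0.63 in the class, so a shift between clusters stays open, and after subtraction of free RNA it was -0.59 (SE 0.284) with the list still past the threshold at the preset correlation (adjusted p = 9.90e-17, against 0.397 before subtraction with an estimated correlation), which argues against free RNA as the whole cause. Sgk1 itself stood between -1.75 and -1.33 in the single clusters, which argues against a shift between clusters for this gene. Of 317 falling regions, 17 had a list member as the nearest gene start, against 65 of 49519 others (Fisher's exact test, two-sided, p = 3.31e-21, with neighbouring regions of a gene counted as independent), and over genes 8 of 20 list members were nearest to a falling region (p = 1.34e-10). This is consistent with a weaker glucocorticoid response, and the hormone level and the handling of the animals were not measured.

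Without TB2, edgeR called 1517 genes in excitatory neurons for TB against CFA, where all 6 libraries gave 0 (1405 at an unadjusted p under 0.05, and 5 by DESeq2), and the size of TB1 or its free RNA could account for it. With classes subsampled to the smallest library 729 genes were called without TB2, 683 of them shared, and after subtraction of free RNA 1492, of which 1411 were shared, so both are unlikely as the sole cause. Predicted gene models made up 52.8% of the falling genes, 2.13% of the rising ones and 16.9% of those tested. The free RNA of TB1 held 5.34% mitochondrial and 3.65% ribosomal counts, against 9.09% to 12.5% and 6.76% to 8.17% in the others (not tested). For CFA against CON, a fit without TB libraries called 51 genes here, against 0 with them. Spread between TB1 and TB2, from animals or preparation, stays open as a cause.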

How the results depend on the processing

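Tests with ambient subtraction, on shared clusters and of lists without single libraries were chosen after the results were seen. DESeq2 size factors left every count of genes and regions within 1.5 times its value and every gene list on its side of the threshold. So did the minimum of 1000 detected genes for counts of genes. The limit to shared clusters left out clusters only in neurons, whose counts stayed at 0. Of 192 counts of genes, 84 moved by more than 1.5 times, as did 69 of 144 counts of regions. Of 729 gene list values, 487 kept direction and side of the threshold, 113 lost the call, 95 gained a call and 34 reversed. Of 634 values for named genes, 542 kept both, 67 lost the call, 24 gained a call and 1 reversed. Of 120 class shares, 19 reversed. With 2 libraries per group, a library left out leaves a lone sample that is assumed to vary like the other groups. Except where the text gives a cause, the cause was not tested. Changes of 2 fold were recovered in 10.4% to 67.2% of simulated cases, so depth and replication limit what can be called.

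Genes called moved to 237 in excitatory neurons, 84 in inhibitory neurons, 92 in astrocytes, 291 in oligodendrocytes and 14 in OPC for CFA against CON and to 572 in excitatory neurons, 422 in inhibitory neurons, 15 in astrocytes, 317 in oligodendrocytes, 6 in OPC and 11 in microglia for TB against CFA without the filter on low counts, which adds genes seen in few libraries. By the Wald test of DESeq2 they moved to 32 in excitatory neurons, 3 in inhibitory neurons, 58 in oligodendrocytes, 0 in OPC and 21 in microglia for CFA against CON and to 5 in excitatory neurons, 1 in inhibitory neurons, 3 in oligodendrocytes and 0 in OPC for TB against CFA. In a fit of only the libraries compared, they moved to 51 in excitatory neurons, 30 in inhibitory neurons, 93 in astrocytes, 20 in oligodendrocytes, 2 in OPC and 37 in microglia for CFA against CON and to 1 in OPC for TB against CFA. A replicate block (pairing unknown) moved them to 96 in astrocytes, 55 in oligodendrocytes and 3 in OPC for CFA against CON and to 1 in OPC for TB against CFA. With doublets kept, they moved to 1 in inhibitory neurons, 0 in oligodendrocytes and 3 in OPC for CFA against CON and to 0 in OPC and 25 in microglia for TB against CFA. Classes subsampled to the smallest library gave 11 in OPC and 23 in microglia for CFA against CON and 1 in oligodendrocytes and 1 in microglia for TB against CFA, with fewer nuclei in the fit. After ambient subtraction, they moved to 0 in oligodendrocytes, 2 in OPC and 5 in microglia for CFA against CON and to 1 in inhibitory neurons, 6 in OPC and 0 in microglia for TB against CFA. With single libraries left out, genes called for CFA against CON ran from 0 to 57 (without TB1) in excitatory neurons, from 0 to 34 (without TB1) in inhibitory neurons and from 0 to 153 (without TB2) in astrocytes. They ran from 0 to 101 (without TB2) in oligodendrocytes, from 1 to 50 (without CFA1) in OPC and from 7 to 134 (without CFA1) in microglia. Those for TB against CFA ran from 0 to 1517 (without TB2) in excitatory neurons, from 0 to 1635 (without TB2) in inhibitory neurons and from 0 to 67 (without TB2) in astrocytes. These ran from 0 to 582 (without TB2) in oligodendrocytes, from 0 to 40 (without TB2) in OPC and from 2 to 15 (without TB2) in microglia.

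Regions called moved to 61 in astrocytes and 4 in OPC for CFA against CON and to 12 in astrocytes and 38 in oligodendrocytes for TB against CFA without the filter on low counts. Fits of only the libraries compared moved them to 2 in inhibitory neurons and 0 in microglia for CFA against CON and to 14 in excitatory neurons and 24 in oligodendrocytes for TB against CFA. A replicate block moved them to 2 in excitatory neurons for CFA against CON and to 9 in astrocytes for TB against CFA. Where each library's peaks had to cover 50% of the region, which tests fewer regions, they moved to 0 in excitatory neurons, 0 in inhibitory neurons and 1 in microglia for CFA against CON and to 0 in excitatory neurons, 0 in inhibitory neurons, 1 in astrocytes and 7 in oligodendrocytes for TB against CFA. The offset for covered length moved them to 0 in excitatory neurons, 0 in inhibitory neurons, 12 in astrocytes and 1 in microglia for CFA against CON and to 0 in excitatory neurons, 0 in inhibitory neurons, 0 in astrocytes and 3 in oligodendrocytes for TB against CFA. With single libraries left out, regions called for CFA against CON ran from 0 to 24 (without CON2) in excitatory neurons, from 3 to 8 (without CON1 or CFA1) in inhibitory neurons and from 12 to 67 (without CFA1) in astrocytes. They ran from 125 to 420 (without CFA1) in oligodendrocytes, from 2 to 13 (without CON1) in OPC and from 1 to 12 (without CON1) in microglia. The counts for TB against CFA ran from 3 to 20 (without CON1) in excitatory neurons, from 5 to 12 (without CFA1) in inhibitory neurons and from 5 to 19 (without CFA1) in astrocytes. These ran from 24 to 39 (without CFA2) in oligodendrocytes, from 2 to 9 (without TB1) in OPC and from 0 to 3 (without CFA2) in microglia.

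No class share passed the threshold, and the log2 ratios only changed sign. With at least 1000 detected genes, the ratio became 0.00055 in inhibitory neurons and 0.043 in microglia for CFA against CON and 0.14 in astrocytes, -0.20 in oligodendrocytes and -0.53 in microglia for TB against CFA. With single libraries left out, the ratio for CFA against CON ran from -0.20 (without CFA2) to 0.083 (CFA1) in inhibitory neurons and from -0.42 (without CFA1) to 0.20 (CFA2) in astrocytes. It ran from -0.26 (without CON2) to 0.027 (CON1) in oligodendrocytes and from -0.48 (without CFA2) to 0.077 (CFA1) in microglia for that contrast. The ratio for TB against CFA ran from -0.0086 (without TB1) to 0.27 (TB2) in excitatory neurons, from -0.032 (without CFA1) to 0.25 (CFA2) in inhibitory neurons and from -0.32 (without CFA2) to 0.31 (CFA1) in astrocytes. It ran from -0.0071 (without TB2) to 0.12 (TB1) in oligodendrocytes, from -0.30 (without CFA2) to 0.043 (CFA1) in OPC and from -0.015 (without CFA1) to 0.55 (CFA2) in microglia.

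With an estimated correlation, all 37 lists past the threshold for CFA against CON lost the call, with an adjusted p of 0.397, 0.42, 0.437, 0.478, 0.484 and 0.691, and all 19 for TB against CFA did so with 0.942. A replicate block let 4 further lists pass for TB against CFA, with an adjusted p of 0.0497 for GABA and glycine genes in excitatory neurons, 0.00728 for ribosomal proteins in excitatory neurons, 0.0396 for heat shock genes in astrocytes and 0.0202 for oxidative phosphorylation in oligodendrocytes. On clusters shared by every library, calls for CFA against CON in inhibitory neurons ended at an adjusted p of 0.165 for cholesterol synthesis genes and 0.0747 for sex-linked genes. For TB against CFA lists newly passed at 0.0334 for voltage-gated and TRP channels and 0.0183 for ribosomal proteins in excitatory neurons, and 0.00293 for mitochondrially encoded genes in inhibitory neurons. After ambient subtraction, lists that newly passed for CFA against CON had an adjusted p in excitatory neurons of 0.0239 for glutamate receptors, 0.00594 for glucocorticoid response genes and 0.0359 for short-chain fatty acid use. It was 0.00952 for glucocorticoid response genes and 0.0406 for heat shock genes in inhibitory neurons, and 0.0392 for cholesterol synthesis genes in oligodendrocytes. For TB against CFA the newly passing values were 2.91e-07 in excitatory neurons, 5.09e-42 in inhibitory neurons and 2.02e-27 in OPC for mitochondrially encoded genes. They were 5.27e-05 in astrocytes and 0.00397 in microglia for ribosomal proteins, and 6.28e-05 in astrocytes and 5.27e-05 in oligodendrocytes for oxidative phosphorylation. They were also 0.043 for histone deacetylases and acetyltransferases in oligodendrocytes and 0.0162 for microglia homeostatic genes in microglia. The subtraction reversed the direction of the test for CFA against CON for mitochondrially encoded genes and for ribosomal proteins in OPC (adjusted p = 0.958). For mitochondrially encoded genes the adjusted p was 3.51e-11 in excitatory neurons, 1.23e-14 in inhibitory neurons, 0.467 in astrocytes, 6.71e-26 in oligodendrocytes, 1.23e-23 in OPC and 0.929 in microglia. For TB against CFA the reversed values of ribosomal proteins were 1.42e-06 in excitatory neurons, 0.00241 in inhibitory neurons and 9.72e-10 in OPC, and the call ended at 0.0686 for heat shock genes in microglia. Direction here is that of the test against the other genes of the class, and the median log2 fold change stayed positive for mitochondrially encoded genes in astrocytes (0.24) and microglia (0.70) and for ribosomal proteins in OPC (0.11). Mitochondrial counts came near 0 in some libraries after subtraction in neurons, oligodendrocytes and OPC, so their folds cannot be read there.

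Lists refitted without single libraries gave these lowest and highest adjusted p for CFA against CON. For a list that had not passed, values cover only the libraries without which it did. Neuropeptides in excitatory neurons gave 0.00104 without CFA1 and 0.313 without CFA2, pain-related receptors 0.00809 without CFA1 and 0.192 without CFA2, and glutamate receptors 0.0224 without CON1 and 0.023 without CFA2. Cholesterol synthesis genes in excitatory neurons gave 0.000115 without CON1 and 0.563 without CON2, circadian clock genes 0.00109 without CON1 and 0.321 without CON2, and heat shock genes 0.00191 without CFA2 and 0.0186 without CFA1 (reversed). Glutamate receptors in inhibitory neurons gave 6.99e-05 without CFA2 and 0.98 without CFA1, voltage-gated and TRP channels 0.00892 without CFA2, and cholesterol synthesis genes 0.00329 without CON1 and 0.49 without CON2. Circadian clock genes in inhibitory neurons gave 0.024 without CFA1 and 0.0383 without CON1, heat shock genes 0.000325 without CFA2, and mitochondrially encoded genes 4.56e-08 without CFA1 and 0.0764 without CFA2. Oxidative phosphorylation in inhibitory neurons gave 2.42e-27 without CFA1 and 0.207 without CFA2, and sex-linked genes 0.00234 without CFA1 and 0.973 without CFA2 (reversed). Immediate early genes in astrocytes gave 0.0189 without CFA1 and 0.0346 without TB1, reactive astrocyte genes 0.00563 without CFA1 and 0.0487 without CON2, and interferon response genes 2.68e-08 without CFA1 and 0.0457 without CON2. Complement genes in astrocytes gave 0.00416 without CFA1 and 0.0484 without TB2, cholesterol synthesis genes 6.85e-08 without CON1 and 0.106 without CON2, and glucocorticoid response genes 0.00208 without CFA1 and 0.187 without CFA2. Sex-linked genes in astrocytes gave 0.00384 without CON1 and 0.0797 without CON2. Interferon response genes in oligodendrocytes gave 6.97e-12 without CFA1 and 0.631 without CFA2 (reversed), myelin genes 0.0472 without CFA1, and heat shock genes 3.31e-08 without CFA1 and 0.0237 without CFA2 (reversed). Histone deacetylases and acetyltransferases in oligodendrocytes gave 0.0388 without CON1. Glucocorticoid response genes in OPC gave 0.00957 without CFA1 and 0.306 without CFA2, heat shock genes 4.92e-09 without CFA1 and 0.183 without CFA2, and mitochondrially encoded genes 5.41e-08 without CFA1 and 0.308 without CFA2. Interferon response genes in microglia gave 3.24e-07 without CFA1 and 0.856 without CFA2, complement genes 0.0402 without CFA1, and glucocorticoid response genes 0.0242 without CON2. Heat shock genes in microglia gave 0.0342 without CON2, and sex-linked genes 0.0215 without CON1 and 0.0462 without CFA1.

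The lowest and highest adjusted p for TB against CFA followed the same order. Neuropeptides in excitatory neurons gave 4.45e-07 without TB1 and 0.0321 without CON1, pain-related receptors 0.000162 without CFA1 and 0.0957 without TB1, and GABA and glycine genes 0.0275 without TB2. Voltage-gated and TRP channels in excitatory neurons gave 0.00307 without CFA1 and 0.0115 without TB2, heat shock genes 3.75e-14 without TB1 and 0.128 without TB2, and histone deacetylases and acetyltransferases 0.00636 without CFA1 and 0.536 without TB1. Mitochondrially encoded genes in excitatory neurons gave 5.94e-05 without TB1 (reversed), ribosomal proteins 1.39e-08 without CFA1 and 0.00201 without TB1 (reversed), and oxidative phosphorylation 9.3e-07 without TB1 (reversed) and 0.035 without CFA2 (reversed). Sex-linked genes in excitatory neurons gave 0.0368 without CFA1. Neuropeptides in inhibitory neurons gave 0.0368 without TB1, pain-related receptors 0.0067 without CON2 and 0.517 without TB1, and glutamate receptors 0.0181 without CFA1. GABA and glycine genes in inhibitory neurons gave 0.00155 without CFA1 and 0.433 without TB1, voltage-gated and TRP channels 0.00272 without CFA1 and 0.0116 without TB2, and histone deacetylases and acetyltransferases 0.00858 without TB2. Mitochondrially encoded genes in inhibitory neurons gave 0.00295 without TB2 and 0.00858 without CFA2, ribosomal proteins 1.64e-09 without TB1 (reversed) and 1.96e-05 without CFA1, and oxidative phosphorylation 1.58e-11 without TB1 and 0.0013 without CFA2. Reactive astrocyte genes in astrocytes gave 0.0103 without CFA1, interferon response genes 4.24e-07 without CFA1 and 0.00148 without CFA2 (reversed), and complement genes 0.0317 without CFA1. Cholesterol synthesis genes in astrocytes gave 4.59e-07 without TB1 and 0.237 without TB2, heat shock genes 2.06e-05 without TB1 and 0.0236 without CFA2, and mitochondrially encoded genes 0.0147 without CFA2. Ribosomal proteins in astrocytes gave 7.54e-09 without TB2 and 0.00909 without CFA2 (reversed), oxidative phosphorylation 5.35e-06 without TB2 and 0.000389 without TB1 (reversed), and sex-linked genes 0.00272 without CFA1 and 0.0813 without TB1. Interferon response genes in oligodendrocytes gave 1.94e-09 without CFA1 and 0.0448 without CFA2 (reversed), cholesterol synthesis genes 0.000168 without TB2 and 0.0781 without TB1, and glucocorticoid response genes 1.77e-05 without CFA1 and 0.599 without CFA2. Heat shock genes in oligodendrocytes gave 1.85e-14 without CFA2 and 0.211 without CFA1, mitochondrially encoded genes 6.72e-05 without CFA2 and 0.904 without CFA1, and ribosomal proteins 2.65e-15 without TB1 and 0.709 without TB2 (reversed). Oxidative phosphorylation in oligodendrocytes gave 2.59e-08 without TB1 and 6.06e-06 without CFA2. OPC genes in OPC gave 0.00266 without CFA2 and 0.352 without CFA1, heat shock genes 8.73e-05 without CFA2 and 0.934 without CFA1 (reversed), and mitochondrially encoded genes 0.000252 without CFA2 and 0.000971 without TB2. Ribosomal proteins in OPC gave 1.49e-07 without CFA1 and 0.83 without CFA2 (reversed). Microglia homeostatic genes in microglia gave 0.0108 without CFA2 and 0.0344 without TB1, microglia activation genes 6.37e-08 without CFA1 and 0.00251 without CFA2 (reversed), and interferon response genes 0.00705 without CFA2 and 0.0193 without CFA1 (reversed). Heat shock genes in microglia gave 0.00909 without CFA2 and 0.344 without CFA1, mitochondrially encoded genes 0.0181 without CFA1, and ribosomal proteins 4.31e-08 without CFA1 and 0.0185 without TB2. Among named genes, only the log2 fold change of Apoe in microglia for TB against CFA, which had not passed, changed sign, from -1.78 without CFA1 to 0.057 without CFA2.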

Other observations

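Rare classes held too few nuclei for tests of genes, and their shares are given as values. Endothelial cells, which line vessels, made up 1.76% and 1.02% of the nuclei in CFA1 and CFA2, against 0.569% and 0.801% in CON and 0.287% and 0.419% in TB. Pericytes, which wrap capillaries, followed the same order, with means of 0.812% in CFA, 0.334% in CON and 0.242% in TB. Fibroblasts and meningeal cells made up 2.94% of CFA1 and between 0.408% and 0.534% of each other library. Committed oligodendrocyte precursors, the stage between OPC and myelin-forming cells, had means of 1.22% in CON, 0.735% in CFA and 0.545% in TB. Cerebellar granule cells, which lie outside the nucleus, made up 0.756% of CON2, 0.498% of TB1 and none of the nuclei of CFA1. Cholinergic neurons had means of 0.406%, 0.605% and 0.644% in CON, CFA and TB.

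Oligodendrocytes split into clusters whose shares of the class differed between libraries. Cluster 0 held 10.9% and 15.3% of the class in CON, 15.4% and 28.8% in CFA, and 37.9% and 38.3% in TB. Cluster 1 held 51.1% and 42.3% in CON, 39.0% and 16.4% in CFA, and 7.70% and 11.7% in TB. These shares were not tested.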
